A study of Homo sapiens with 24 samples.

How the data were processed

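RNA was sequenced from THP-1 cells in 24 libraries. They came from 4 groups, WT and TET2 KO cells untreated or with 100 ng/ml IFNγ for 20 hours, each with 3 replicates and 2 technical repeats per replicate. The authors deposited whole-number read counts per gene, with genes given as Entrez identifiers and 1 column per library, and all columns were used. Their processing notes name Bowtie2 2.3.2 and the builds hg19 and GRCh37. The counting program, the annotation it used and the strand setting are not given in the sources used here. The table holds 25702 genes, of which 4292 had no count in any library. Symbols were taken from an annotation of a later build, used for names and for the GC content of transcripts only, so no coordinates are given. It named 23696 identifiers, and the other 2006, with 0.441% of the counts, are outside the gene lists.

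Technical repeats of a replicate varied 1.11 to 1.26 times as much as Poisson sampling allows, and were summed to 12 replicates. Totals per replicate ran from 14.9 to 76.6 M counts, and those of single libraries from 7.40 to 38.3 M. A gene with no count in a group was given a floor of 3 counts over the group. Ratios against 1 to 3 counts are given with a 95% counting interval. The table gives counts for whole genes, so it shows neither alleles nor the edit in TET2.

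Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups as design (minimum count 10, minimum total 15), which left 15616 genes. Normalization factors were TMM. A negative binomial model with a term per group was fitted to all 12 replicates, which share the estimate of the spread, and 5 comparisons were tested with the two-sided quasi-likelihood F test. These were IFNγ against no treatment in WT and in TET2 KO cells, TET2 KO against WT without and with IFNγ, and the difference between genotypes in the IFNγ response. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison. Calls with an absolute log2 fold change of at least 1 were counted as well. Fitted log2 fold changes carry edgeR's prior count of 0.125, and levels are TMM-scaled counts per M.

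Gene lists, 31 in number, were written down for signalling, effector, differentiation, stress and metabolic genes and for markers of other cell types. They were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Lists needed at least 3 tested members, so 30 were tested. Calls among members were also counted adjusted over the list alone. Sets of IFNγ-induced and IFNγ-repressed genes were chosen by the average response of both genotypes (adjusted p under 0.05 and a change of at least 1), and their camera p-values are not adjusted.

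Genes named in the text follow a rule. In every comparison they are TET2, CXCL9, CXCL10, CXCL11, CD274, IRF1, JAK2, IFNGR1 and CIITA. To these come the 8 called genes with the largest change in each direction, with an average log2 CPM of at least 2 and no overlap between the replicates compared (the last not asked of the difference of the response), and up to 4 members of each list. Some of the genes and lists tested are not reported here. The lists, the tests, this rule and the alternatives were set before the data were examined, except for 3 alternatives added later, namely robust dispersion estimates, limma-voom with library weights, and a fit without mitochondrial genes.

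Alternatives set in advance were normalization by DESeq2 1.42.0 size factors or by library totals alone, no filter on low counts or an average log2 CPM of at least 1, the Wald test of DESeq2, limma-voom, replicate number as a block, each technical repeat alone, a fit of only the 2 groups compared, each replicate left out in turn, an adjusted p under 0.01, sets chosen on the WT response alone or with a change of at least 2, and the list tests with an estimated correlation. In settings that leave a group with fewer replicates, that group is assumed to vary like the others. Other splits of the samples were fitted as well. On simulated data of the same design, with 200 of 15616 genes changed, 72.7 to 93.9% of changes of 4-fold, 8.96 to 55.2% of changes of 2-fold and 0 to 7.46% of changes of 1.5-fold were recovered, with 3 to 8 false calls per comparison. The simulated spread was that of the fit to all replicates, WT untreated replicate 1 included. Only genes averaging at least 1 CPM were changed. The tests were also checked with lists of known direction. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.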

Results

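RNA was sequenced from THP-1 cells, a human monocytic leukaemia line. Control cells, labelled WT, and cells in which TET2 had been knocked out by CRISPR (TET2 KO) were left untreated or received 100 ng/ml interferon gamma (IFNγ) for 20 hours. TET2 encodes an enzyme that oxidises 5-methylcytosine in DNA, and IFNγ is a cytokine that signals through the kinases JAK1 and JAK2. The question set by the design was how the RNA changes with IFNγ differ between knockout and control cells. Each of the 4 groups had 3 replicates, and each replicate was sequenced in 2 technical repeats, whose counts were summed. The labels do not say whether the replicates were separate cultures or how many knockout clones were used, so errors and p-values describe the spread between these samples.

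Counts per replicate came to 14.9, 76.6 and 61.9 M in WT untreated replicates 1, 2 and 3, and to 43.7, 49.9 and 71.5 M in WT IFNγ. They came to 40.1, 44.5 and 31.5 M in TET2 KO untreated, and to 31.2, 33.2 and 31.6 M in TET2 KO IFNγ. WT untreated replicate 1 stood apart. Mitochondrial genes took 12.4% of its counts, against 9.67% and 6.51% in TET2 KO IFNγ replicates 1 and 2 and 3.07 to 4.13% in the other 9 replicates. Its counts varied 399.8 and 371 times as much as Poisson sampling allows against WT untreated replicates 2 and 3, which varied 2.21 times as much between themselves. The total number of genes called in each comparison is therefore followed below by the number without that library, a setting that was planned for every replicate. Counts within lists and sets, of larger changes and of shared genes come from all replicates unless stated otherwise. Levels are TMM-scaled CPM, counts scaled to the library total times its TMM factor, with the SD over 3 replicates. Changes are log2 fold changes from edgeR, unless stated otherwise. The value after ± of a change is an approximate standard error, the size of the change divided by the square root of its F statistic. Intervals and floors cover counting error only.

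**Figure D1:**
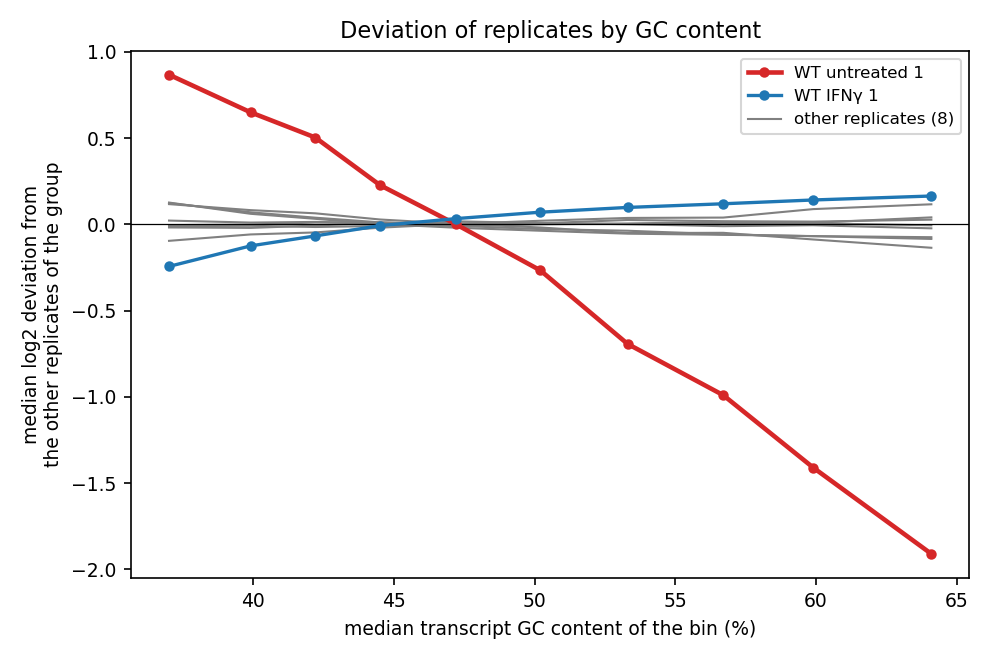
Median log2 deviation of each replicate from the other replicates of its group (vertical axis) in bins of genes ordered by transcript GC content in percent (horizontal axis), with WT untreated replicate 1 in red, WT IFNγ replicate 1 in blue and the other 8 replicates drawn in grey. WT untreated replicate 1 runs from 0.87 in the lowest bin to -1.91 in the highest. WT untreated replicates 2 and 3 are not drawn, since replicate 1 is among the samples they would be set against.

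TET2 RNA (Entrez gene 54790) was present in all 4 groups. Its level was 57.7 ± 10.3 CPM in untreated WT cells, 38.8 ± 2.04 in WT cells with IFNγ, 51.1 ± 7.94 in untreated TET2 KO cells and 56.1 ± 2.66 in TET2 KO cells with IFNγ. Without IFNγ, knockout and control cells differed by -0.17 ± 0.15 (adjusted p = 0.486). With IFNγ, the level was higher by 0.53 ± 0.15 in the knockout (adjusted p = 0.0292), and in WT cells it fell by 0.57 ± 0.15 with IFNγ (adjusted p = 0.0229). The knockout difference with IFNγ lost its call without any single replicate of the groups compared, with differences of 0.48 to 0.57 (adjusted p up to 0.107). The fall in WT cells lost its call without any single WT IFNγ replicate, with changes of -0.60 to -0.53 (adjusted p up to 0.0945), and in a fit of these 2 groups alone (-0.52, adjusted p = 0.133). It did so, just above the threshold and at -0.51, without TET2 KO untreated replicate 1 or 2 or TET2 KO IFNγ replicate 2 or 3. The response of TET2 differed between genotypes by 0.70 ± 0.21 (adjusted p = 0.0903), and by 0.51 (adjusted p = 0.0208) without WT untreated replicate 1. A table of counts per gene cannot show a small edit within the gene, so these values neither show nor exclude it.

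In control cells, IFNγ raised the RNA of the T cell-attracting chemokines that bind CXCR3 and of CD274, which encodes the immune checkpoint ligand PD-L1. CXCL10 (Entrez gene 3627) went from 0.739 ± 0.759 to 299.8 ± 11.8 CPM, CXCL9 (4283) from 0.255 ± 0.409 to 47.0 ± 1.39 and CD274 (29126) from 0.431 ± 0.0619 to 54.01 ± 1.79. The change of CXCL10 was 9.22 ± 0.59, or 9.96 without WT untreated replicate 1, and the untreated level of CXCL9 rested on that replicate, at 0.726 CPM against 0.0376 and 0 in the others. CXCL11 (6373) had 0 counts in untreated WT cells and 21.2 ± 4.01 CPM with IFNγ. By counts pooled over the group it was at least 1138-fold higher, against a floor of 3 counts over the untreated group. IRF1 (3659), a transcription factor of the interferon response, rose from 31.6 ± 8.37 to 890.5 ± 42.2 CPM. CIITA (4261), the activator of MHC class II genes, rose from 0.519 ± 0.458 to 33.3 ± 2.79. JAK2 (3717) rose by 1.82 ± 0.22, while IFNGR1 (3459), a chain of the IFNγ receptor, gave -0.33 ± 0.10 and did not pass (adjusted p = 0.0526, against 0.0297 without WT untreated replicate 1 and 0.00954 with DESeq2). Adjusted p-values of the genes that rose ran from 5.63e-09 for CD274 to 2.19e-04 for JAK2.

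The fixed gene lists that define an interferon response rose together in WT cells. All 5 tested members of the list of CXCR3 and PD-1 ligands rose (5 adjusted over the list alone, median 8.98, camera adjusted p = 6.67e-25). Of 9 guanylate-binding proteins and related GTPases, which act against intracellular microbes, 7 rose (8, with 1 fall, adjusted over the list alone, median 6.57, adjusted p = 2.55e-39), among them GBP1 at 11.41 ± 0.55 and GBP5 at 6.81 ± 0.19. Of 46 antiviral interferon-stimulated genes, 42 rose and 1 fell (43 and 1 adjusted over the list alone, median 3.06, adjusted p = 5.57e-114). IFITM1 and TRIM22, which restrict viruses, changed by 4.82 ± 0.12 and 5.14 ± 0.17.

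Antigen presentation moved with them. In the MHC class I list, 20 of 22 members rose (20 adjusted over the list alone, median 1.65, adjusted p = 6.57e-31), including the peptide transporter TAP1 at 5.04 ± 0.26, the immunoproteasome subunit PSMB9 at 3.56 ± 0.14 and HLA-E at 2.35 ± 0.12. In the MHC class II list, 15 of 19 rose and 1 fell (15 and 1 adjusted over the list alone, median 3.16, adjusted p = 7.98e-51), with HLA-DRA at 6.86 ± 0.27 and HLA-DPA1 at 6.38 ± 0.21. Reads of HLA paralogs may be shared between them, and the table does not say how such reads were counted. Of 9 tryptophan, pteridine and itaconate enzymes, 6 rose and 1 fell (6 and 1 adjusted over the list alone, median 4.44, or 4.03 with a gene near 0 counts at its bound, adjusted p = 1.09e-19). WARS1, the tryptophanyl-tRNA synthetase, changed by 4.53 ± 0.14, and GCH1, the entry enzyme of biopterin synthesis, by 4.44 ± 0.21. IDO1, which degrades tryptophan, was 1838 times its level on 1 count, in replicate 2, of the untreated group (95% counting interval 329.5 to 72640).

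Effector genes of phagocytes also rose. Of 25 Fc receptor and complement genes, 14 rose and 3 fell (14 and 3 adjusted over the list alone, median 2.39, adjusted p = 2.23e-24), with the C1 inhibitor SERPING1 at 8.14 ± 0.21. That list counts FCGR1A and FCGR1CP, a pseudogene of the same family, as separate genes, and their reads may be shared. Of 27 inflammasome and cell death effectors, 13 rose and 1 fell (17 and 1 adjusted over the list alone, median 0.67, adjusted p = 8.53e-18), with the DNA sensor AIM2 at 8.49 ± 0.25 and the death receptor FAS at 4.82 ± 0.21. Of 9 phagocyte oxidase genes, 4 rose (4 adjusted over the list alone, median 0.81, adjusted p = 1.11e-04), with CYBB, the catalytic subunit, at 3.71 ± 0.21. Of 22 cytokine genes, 9 rose and 1 fell (10 and 3 adjusted over the list alone, median 0.97, adjusted p = 4.97e-06), with IL18BP, which neutralises IL-18, at 4.60 ± 0.21. These 4 lists and the 6 before them also passed with an estimated correlation. Among genes that fell, GPR183, a receptor for oxysterols, changed by -4.01 ± 0.37 and CD84, a signalling receptor of leukocytes, by -2.47 ± 0.13. SERPINB2, an inhibitor of plasminogen activators, changed by -2.38 ± 0.28.

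In 4 further lists the call in WT cells was lost with an estimated correlation. NF-kB targets and regulators had 12 members that rose and 1 that fell of 22 (13 and 1 adjusted over the list alone, adjusted p = 7.46e-06, and adjusted p = 0.0792 with an estimated correlation). T cell co-signalling ligands had 10 of 23 that rose (13, with 4 falls, adjusted over the list alone, adjusted p = 5.41e-05, and adjusted p = 0.0792 with an estimated correlation). The list of MYC and ribosome biogenesis had 7 of 24 that rose (9 adjusted over the list alone, adjusted p = 0.0146, and adjusted p = 0.399 with an estimated correlation). The list of monocyte and macrophage differentiation had 10 that rose and 5 that fell of 40 (12 and 6 adjusted over the list alone, adjusted p = 0.0285, and adjusted p = 0.536 with an estimated correlation), and lost its call without WT untreated replicate 1 (adjusted p = 0.0574). The remaining 15 lists tested did not pass, with adjusted p from 0.0521 for HOXA, MEIS1 and partners, to 0.998 for immediate early genes. The HOXA list passed without WT untreated replicate 2, TET2 KO untreated replicate 1 or 3, or TET2 KO IFNγ replicate 1 or 3 (lowest adjusted p = 0.0304), and hypoxia and glycolysis without WT untreated replicate 3 (adjusted p = 0.0424). In the lists of germline genes, p53 targets, heat shock genes, immediate early genes, sterol genes and epithelial, fibroblast and endothelial markers, the median, mean and test differed in sign.

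Of 15616 genes tested, 2884 changed in WT cells, 1403 up and 1481 down, and 1368 of them (719 up and 649 down) by at least 1 on the log2 scale. Without WT untreated replicate 1 the number was 6073 (3233 up and 2840 down). It was 1536 to 1561 without any single WT IFNγ replicate, with 57.63% to 58.33% up, and 1034 (708 up and 326 down) in a fit of these 2 groups alone. It was 1348 (797 up and 551 down) at an adjusted p under 0.01 and 10548 with library weights in limma-voom, a setting added after the data were seen. Scaled by library totals alone, 1116 rose and 1778 fell, while without any single TET2 KO replicate 50.73% to 59.42% rose. Which direction held more genes thus turned with the setting, also among changes of at least 1, where 824 rose and 1050 fell without WT untreated replicate 2.

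In TET2 KO cells, IFNγ also raised the RNA of CXCL10 and CD274. CXCL10 went from 3.35 ± 0.239 to 67.3 ± 21.9 CPM, a change of 4.32 ± 0.45 (adjusted p = 0.00163), and CD274 from 0.362 ± 0.0638 to 1.59 ± 0.35, a change of 2.13 ± 0.21 (adjusted p = 0.0012). GBP1 changed by 3.95 ± 0.39, ETV7, a transcriptional repressor, by 2.81 ± 0.27 and SERPING1 by 2.81 ± 0.17. CXCL9 was 213 times its untreated level on 3 counts, all in replicate 1, of the untreated group (95% counting interval 72.5 to 1036, adjusted p = 0.0164), and CXCL11 changed by 1.80 ± 0.23 (adjusted p = 0.0186). CXCL9 lost its call without any single replicate of WT IFNγ or TET2 KO untreated and without TET2 KO IFNγ replicate 1 or 2, and with limma-voom (adjusted p = 0.0728). CXCL11 lost its call without WT IFNγ replicate 2 or 3, TET2 KO untreated replicate 1 or 2, or any TET2 KO IFNγ replicate (adjusted p up to 0.189 for each), and with technical repeat 2 only (1.77, adjusted p = 0.0848). IRF1 (1.02 ± 0.17, adjusted p = 0.0583), JAK2 (0.20 ± 0.22, adjusted p = 1.00), IFNGR1 (-0.04 ± 0.10, adjusted p = 1.00) and CIITA (0.41 ± 0.50, adjusted p = 1.00) did not pass. Without WT untreated replicate 1, however, IRF1 passed with a change of 1.02 (adjusted p = 5.51e-06), as it also did with DESeq2 and in a fit of these 2 groups alone.

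Several of the fixed lists rose together in the knockout as well. Of the CXCR3 and PD-1 ligands, 4 of 5 rose (4 adjusted over the list alone, median 2.13, camera adjusted p = 4.58e-58). Of the guanylate-binding proteins and related GTPases, 4 of 9 rose (4 adjusted over the list alone, median 0.96, adjusted p = 1.81e-53). Of 46 antiviral genes, 6 rose (12 adjusted over the list alone, median 0.32, adjusted p = 4.37e-63), with TRIM22 at 1.88 ± 0.15 and EPSTI1 at 2.11 ± 0.18. In the Fc receptor and complement list 1 of 25 rose (4 adjusted over the list alone, median 0.18, adjusted p = 1.66e-15), and among the tryptophan, pteridine and itaconate enzymes 1 of 9 (3 adjusted over the list alone, median 0.21, adjusted p = 1.56e-06). The cytokine list passed with 0 of 22 members past the threshold (2 adjusted over the list alone, median 0.24, adjusted p = 3.26e-06). The inflammasome and cell death list passed with 1 of 27 (2 adjusted over the list alone, adjusted p = 2.99e-04), but its median of 0.02 turned to -0.01 without TET2 KO IFNγ replicate 2 and to -0.02, with the call lost, without replicate 3.

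Antigen presentation lists did not pass in the knockout. No member of the MHC class I list (22 tested, median 0.02, adjusted p = 0.187) or of the MHC class II list (19 tested, median -0.00094, adjusted p = 0.268) passed over all genes or adjusted over the list alone. The MHC class I list passed, with medians of 0.01, without WT untreated replicate 1 (adjusted p = 0.0204) and without TET2 KO untreated replicate 1 (adjusted p = 0.0346). HLA-DRA stood at 3.78 ± 0.0494 CPM untreated and 3.93 ± 0.718 with IFNγ, and TAP1 at 96.9 ± 3.28 and 175 ± 20.2. The calls of 3 lists were lost with an estimated correlation. They were other chemokines (0 of 15 members past the threshold, adjusted p = 9.08e-05, and adjusted p = 0.0626 with an estimated correlation) and immediate early genes (0 of 23, and 1 adjusted over the list alone, adjusted p = 0.00289, and adjusted p = 0.297 with an estimated correlation). Sterol synthesis and uptake had a median of -0.12 (0 of 26, adjusted p = 0.00289, and adjusted p = 0.116 with an estimated correlation). The lists of chemokines and immediate early genes also lost their calls without TET2 KO IFNγ replicate 3 (adjusted p = 0.155 and 0.0557). The other 19 lists, the MHC lists included, did not pass. Of these, the lists of NF-kB targets and of MYC and ribosome biogenesis passed without WT untreated replicate 1 (adjusted p = 0.0274 and 0.0204). NF-kB also passed without TET2 KO untreated replicate 3 or TET2 KO IFNγ replicate 1, and MYC without TET2 KO untreated replicate 1 or 2 or TET2 KO IFNγ replicate 3. The cell cycle list passed without TET2 KO untreated replicate 3 or TET2 KO IFNγ replicate 1, the monocyte list without the latter, and the phagocyte oxidase list without WT IFNγ replicate 1 or 3 or TET2 KO IFNγ replicate 2. Where they did, medians stayed between -0.10 and 0.14. In the lists of DNA methylation machinery, p53 targets and B cell markers the median and the test differed in sign.

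In all, 24 genes changed in TET2 KO cells and all 24 rose, 21 of them by at least 1 on the log2 scale, while 177 genes had an unadjusted p under 0.05. Without WT untreated replicate 1 the number was 52. All 24 also rose in WT cells with a larger change there, where 2.16 would be shared if the calls were independent. The number was 12 or 13 without TET2 KO untreated replicate 1 or 2 or TET2 KO IFNγ replicate 1 or 2, 12 at an adjusted p under 0.01 and 41 (40 up and 1 down) with DESeq2. It was 225 (198 up and 27 down) with library weights. In simulated data with this design, 87.9% of changes of 4-fold and 37.3% of changes of 2-fold were recovered, so smaller responses may have gone undetected here.

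**Figure D2:**
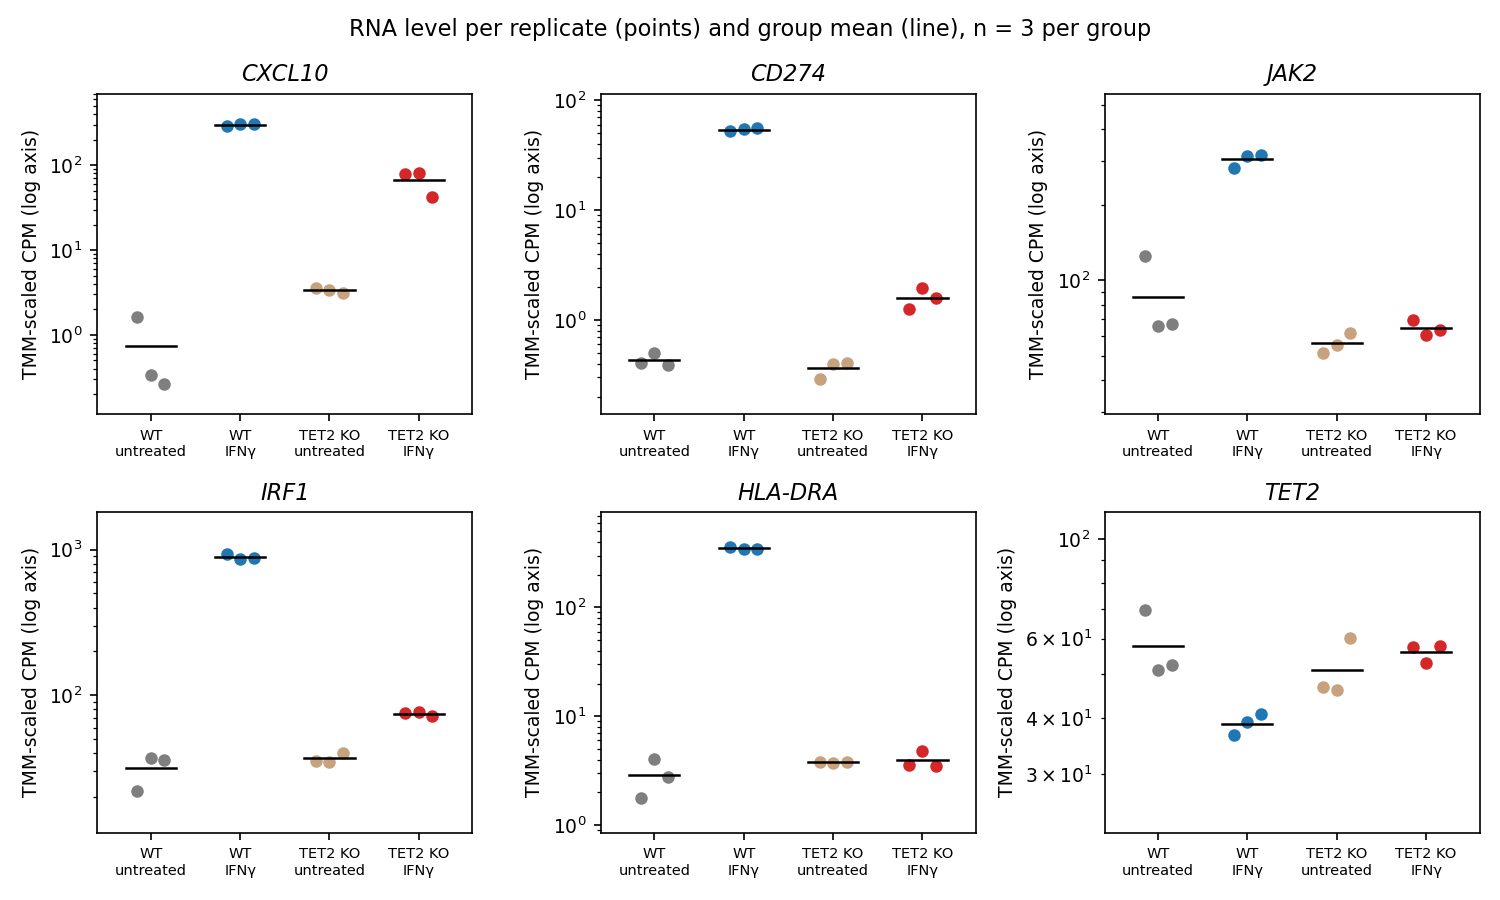
Level of 6 RNAs in each replicate (points) with the group mean (line, n = 3), in TMM-scaled CPM on log axes. CXCL10, CD274, JAK2, IRF1 and HLA-DRA are highest in WT cells with IFNγ, where CD274 reaches 54.01 CPM against 1.59 in TET2 KO cells with IFNγ. TET2 lies between 36.7 and 69.5 in all replicates.

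The test of the question itself is the difference between the IFNγ responses of the genotypes, TET2 KO minus WT. The response was smaller in the knockout for CD274, CXCL10, CXCL11, IRF1, JAK2 and CIITA. The difference on the log2 scale was -4.80 ± 0.30 for CD274 (adjusted p = 2.83e-06). It was -4.89 ± 0.65 for CXCL10 (adjusted p = 9.94e-04, and -5.65 without WT untreated replicate 1) and -3.79 ± 0.25 for IRF1 (adjusted p = 3.58e-06). It was -1.62 ± 0.31 for JAK2 (adjusted p = 0.0103) and -5.28 ± 0.70 for CIITA (adjusted p = 9.33e-04). CXCL11 differed as well (adjusted p = 5.54e-06). Its group means rose by at least 10.12 in WT cells, from the floor of 3 counts, and by 1.79 in TET2 KO cells. Part of the difference for CXCL10 and CXCL11 lay in higher untreated levels in TET2 KO cells (3.35 and 1.43 CPM) than in WT cells (0.739 and 0). With IFNγ they stood at 67.3 and 4.96 CPM in TET2 KO cells against 299.8 and 21.2 in WT cells. CXCL9 (-1.37 ± 2.46, adjusted p = 0.794), with few counts in both untreated groups, and IFNGR1 (0.29 ± 0.15, adjusted p = 0.33) did not pass. With library weights they did (-3.44 and 0.20, adjusted p = 0.00869 and 0.0324), and without TET2 KO untreated replicate 1, which held all CXCL9 counts of that group, the CXCL9 difference turned positive. Of the 24 genes that rose in TET2 KO cells, 23 had a significantly smaller response than in WT cells, and the exception was CXCL9.

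A total of 16 of the 30 lists tested passed for this difference, 11 of them also with an estimated correlation, and all 11 had a smaller response in the knockout. Of 46 antiviral genes, 38 had a smaller response (41 adjusted over the list alone, median -2.58, camera adjusted p = 1.09e-111), such as IFIT3 at -5.21 ± 0.28 and OAS2, a sensor of viral RNA, at -4.12 ± 0.24. The count was 13 of 19 for MHC class II (13 adjusted over the list alone, median -3.33, adjusted p = 6.30e-52), with HLA-DRA at -6.80 ± 0.34. For MHC class I it was 16 of 22 (20 adjusted over the list alone, median -1.65, adjusted p = 4.09e-35), with TAP1 at -4.19 ± 0.33. It was 6 of 9 for guanylate-binding proteins and related GTPases (6 adjusted over the list alone, median -5.60, adjusted p = 2.58e-36). It was 4 of 5 for CXCR3 and PD-1 ligands (4 adjusted over the list alone, median -4.80, adjusted p = 2.38e-16).

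Smaller responses were also found for 5 of 9 tryptophan, pteridine and itaconate enzymes (6, with 1 in the other direction, adjusted over the list alone, median -3.67, or -3.21 with a gene near 0 counts at its bound, adjusted p = 9.08e-24), with WARS1 at -3.67 ± 0.18. They were found for 11 of 25 Fc receptor and complement genes, against 1 in the other direction (13 and 3 adjusted over the list alone, median -2.37, adjusted p = 1.86e-19), with SERPING1 at -5.34 ± 0.25. The same held for 9 of 27 inflammasome and cell death effectors (12, with 1 in the other direction, adjusted over the list alone, median -0.62, adjusted p = 1.04e-16), with AIM2 at -6.71 ± 0.32. It held for 3 of 9 phagocyte oxidase genes (4, with 1 in the other direction, adjusted over the list alone, median -0.73, adjusted p = 1.71e-04), with CYBB at -3.74 ± 0.28. Of 22 cytokine genes, 6 had a smaller response, with 1 in the other direction (7 and 1 adjusted over the list alone, median -0.13, adjusted p = 2.98e-05), with IL18BP at -4.13 ± 0.28 and CSF1, the macrophage growth factor, at -5.23 ± 0.43. Some genes that IFNγ lowered in WT cells had positive differences, among them GPR183 at 3.90 ± 0.47, GAPT at 3.83 ± 0.67 (2.85 without WT untreated replicate 1) and SERPINB2 at 2.43 ± 0.39.

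The calls of 5 lists for this difference were lost with an estimated correlation. Among them were NF-kB targets and regulators (5 of 22 with a smaller response, 8 and 1 in the other direction adjusted over the list alone, adjusted p = 5.18e-06, and adjusted p = 0.0735 with an estimated correlation), where ICAM1, an adhesion molecule, stood at -4.57 ± 0.47. T cell co-signalling ligands were another (7 of 23, 11 adjusted over the list alone, adjusted p = 5.65e-06, and adjusted p = 0.0537 with an estimated correlation), where BTN3A1 stood at -2.13 ± 0.24. Further lists were MYC and ribosome biogenesis (1 of 24, 0 adjusted over the list alone, adjusted p = 0.0345, and adjusted p = 0.49 with an estimated correlation) and monocyte and macrophage differentiation (6 of 40, 8 and 5 in the other direction adjusted over the list alone, adjusted p = 0.0162, and adjusted p = 0.515 with an estimated correlation). HOXA, MEIS1 and partners had a positive median of 0.52 (2 of 20 up and 1 down, the same adjusted over the list alone, adjusted p = 0.0231, and adjusted p = 0.161 with an estimated correlation). Leaving out single replicates also ended these last 3 calls, that of HOXA without WT untreated replicate 1 (adjusted p = 0.0668). The call of the monocyte list ended without TET2 KO untreated replicate 3 or TET2 KO IFNγ replicate 1 (adjusted p = 0.0927 and 0.0504). That of MYC ended without WT untreated replicate 2 or 3, TET2 KO untreated replicate 1 or 2, or TET2 KO IFNγ replicate 3 (adjusted p up to 0.109). The other 14 lists did not pass, hypoxia and glycolysis excepted without WT untreated replicate 3 or TET2 KO untreated replicate 3 (adjusted p = 0.0332 and 0.0284). Among them, adjusted p was 0.755 for other chemokines, 0.404 for the cell cycle, 0.294 for granulocyte precursor and progenitor genes, 0.294 for DNA methylation machinery, 0.984 for germline genes, 0.302 for p53 targets, 0.472 for the unfolded protein and amino acid stress response, 0.962 for heat shock, 0.485 for immediate early genes, 0.0912 for hypoxia and glycolysis and 0.67 for sterol synthesis and uptake. The median and mean of the germline list differed in sign, as did the chemokine median once genes at 0 counts were put at their bounds.

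Over the genes that IFNγ changed on average in both genotypes, the response in the knockout was a small part of that in WT cells. This choice leaves the difference untilted only where the groups vary alike. WT untreated replicate 1 varied more, so the choice can tilt the difference toward a smaller response in the knockout. With the same induced genes and without that library, however, their median difference was -2.82. The median of 331 induced genes was 3.18 in WT and 0.33 in TET2 KO cells, and their median difference was -2.81. Of them, 328 had a negative difference (260 significantly, camera p = 5.15e-293, and p = 5.33e-08 with an estimated correlation). The median of 73 repressed genes was -2.16 in WT and -0.20 in TET2 KO cells, with a median difference of 1.95 (46 significantly positive, camera p = 2.70e-44, and p = 0.000289 with an estimated correlation). In these sets 8 genes had 0 counts in a group, so their fitted changes are not bounds.

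**Figure D3:**
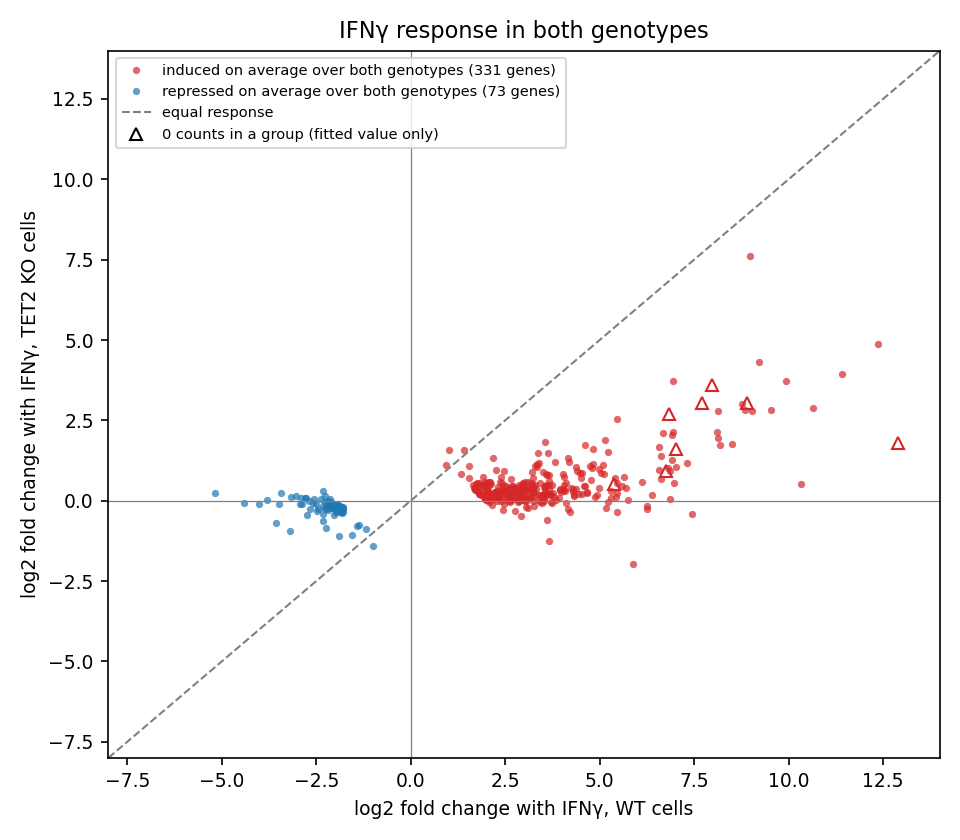
Log2 fold change with IFNγ in WT cells (horizontal axis) and in TET2 KO cells (vertical axis) for the 331 induced and 73 repressed genes, each point a gene, from 3 replicates per group, with open triangles for the 8 genes at 0 counts in a group. Most points lie close to a change of 0 in TET2 KO cells (medians 0.33 and -0.20) and far from the dashed line of equal response.

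In all, 808 genes differed in their response, 282 with a positive and 526 with a negative difference, 613 of them (193 and 420) by at least 1 on the log2 scale. Without WT untreated replicate 1 the number was 3350. It was 484 to 511 without WT IFNγ replicate 2 or 3 or TET2 KO untreated replicate 1 or 2, 403 at an adjusted p under 0.01 and 1548 with DESeq2. With library weights it was 7185, and positive differences were then the larger part (3802 against 3383, and 966 against 720 of at least 1). The positive share of 34.9% fell to 19.76% without TET2 KO untreated replicate 2, its lowest.

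With IFNγ present in both, TET2 KO cells had lower levels of the IFNγ-induced genes than WT cells. IRF1 stood at 74.9 ± 2.94 CPM against 890.5 ± 42.2 (-3.57 ± 0.19, adjusted p = 2.88e-07) and CIITA at 1.12 ± 0.493 against 33.3 ± 2.79 (-4.88 ± 0.50, adjusted p = 4.36e-05). CD274 differed by -5.08 ± 0.19 (adjusted p = 3.48e-08), CXCL10 by -2.15 ± 0.41, CXCL11 by -2.10 ± 0.22 and JAK2 by -2.23 ± 0.23. CXCL9 differed by -3.13 ± 0.62, a call lost with DESeq2, while IFNGR1 was higher by 0.82 ± 0.11 (adjusted p = 2.47e-04). Among the largest falls was HLA-DPB1 at -7.00 ± 0.41, and MX1, an antiviral GTPase, differed by -5.81 ± 0.26. C4A (-6.14 ± 0.26) and C4B (-6.16 ± 0.28), complement genes with near-identical sequences whose reads may be shared, were also lower.

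In the lists, 15 of 19 MHC class II genes (16 adjusted over the list alone, median -3.10, camera adjusted p = 4.11e-48) and 19 of 22 MHC class I genes (21 adjusted over the list alone, median -1.30, adjusted p = 2.36e-23) were lower in the knockout. All 5 CXCR3 and PD-1 ligands were lower (5 adjusted over the list alone, median -2.15, adjusted p = 2.63e-09). So were 34 of 46 antiviral genes, against 1 higher (36 and 1 adjusted over the list alone, median -1.61, adjusted p = 2.81e-52), and 6 of 9 guanylate-binding proteins and related GTPases, against 1 higher (7 and 1 adjusted over the list alone, median -3.71, adjusted p = 3.49e-18). Inflammasome and cell death effectors were lower as a list (15 of 27 lower, 15 adjusted over the list alone, adjusted p = 7.77e-14). So were Fc receptor and complement genes (12 of 25 lower and 6 higher, 13 and 8 adjusted over the list alone, adjusted p = 3.04e-10) and tryptophan, pteridine and itaconate enzymes (4 of 9 lower and 2 higher, 4 and 3 adjusted over the list alone, adjusted p = 9.67e-04).

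The list of other chemokines was higher in TET2 KO cells with IFNγ, with 7 of 15 members higher (10, with 1 lower, adjusted over the list alone, median 2.04, adjusted p = 3.02e-07). Examples were CCL5, which attracts T cells, at 3.01 ± 0.14 and CXCL8, which attracts neutrophils, at 3.16 ± 0.33. These lists also passed with an estimated correlation. The calls of 4 lists were lost with it. They were NF-kB targets and regulators (11 of 22 higher and 2 lower, 13 and 4 adjusted over the list alone, adjusted p = 3.95e-04, and adjusted p = 0.19 with an estimated correlation) and monocyte and macrophage differentiation (16 of 40 higher and 7 lower, 18 and 9 adjusted over the list alone, adjusted p = 0.0102, and adjusted p = 0.546 with an estimated correlation, lost too without WT untreated replicate 1, adjusted p = 0.0621). The other two were immediate early genes (5 of 23 higher and 1 lower, 6 and 1 adjusted over the list alone, adjusted p = 0.0056, and adjusted p = 0.388 with an estimated correlation) and sterol synthesis and uptake (6 of 26 lower, 8 adjusted over the list alone, adjusted p = 0.0056, and adjusted p = 0.135 with an estimated correlation). The other 16 lists did not pass, although the T cell co-signalling, MYC and granulocyte precursor lists did without WT untreated replicate 1 (adjusted p = 0.0431, 0.0369 and 0.0467), and MYC without TET2 KO untreated replicate 3 or TET2 KO IFNγ replicate 1 as well (adjusted p = 0.0311 and 0.0225). In those of the amino acid stress response, heat shock, hypoxia, germline and T cell and NK cell genes the median, mean and test differed in sign.

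The 331 induced genes had a median of -2.11 (255 lower and 11 higher, camera p = 2.28e-141, and p = 1.21e-05 with an estimated correlation) and the 73 repressed genes a median of 1.46 (43 higher and 2 lower, camera p = 1.22e-18, and p = 0.00662 with an estimated correlation). In this comparison 2855 genes differed, 1601 higher and 1254 lower in the knockout, 1641 of them (973 and 668) by at least 1 on the log2 scale. Without WT untreated replicate 1, which is in neither group but shares the estimate of the spread, the number was 7780, with more lower (4121) than higher (3659). It was 1874 without WT IFNγ replicate 3, 7203 in a fit of these 2 groups alone (3422 higher and 3781 lower), 1695 at an adjusted p under 0.01 and 9117 with library weights.

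Without IFNγ, TET2 KO cells already differed from WT cells, with higher RNA of inflammatory genes. S100A8 and S100A9, the subunits of calprotectin, stood at 206 ± 17.9 and 686 ± 54 CPM against 9.01 ± 4.18 and 37.5 ± 8.77, differences of 4.48 ± 0.31 and 4.19 ± 0.18 (adjusted p = 6.53e-06 and 1.88e-07). The cytokine TNF was higher by 3.36 ± 0.18 (adjusted p = 1.09e-06), the NF-kB inhibitor TNFAIP3 by 3.06 ± 0.21 (adjusted p = 6.98e-06) and the complement component C3 by 4.99 ± 0.38 (adjusted p = 1.22e-05). CXCL11, at 0 counts in WT cells, stood at 1.43 ± 0.377 CPM in TET2 KO cells, at least 73.2-fold higher by counts pooled over the group. CXCL10 was higher by 2.74 ± 0.51 (adjusted p = 0.00556), or by 3.47 without WT untreated replicate 1, a call lost in a fit of these 2 groups alone (2.49, adjusted p = 0.16). IFNGR1 was higher by 0.53 ± 0.11 (adjusted p = 0.0076), a call lost in that same fit (0.55, adjusted p = 0.136). CD274 (-0.28 ± 0.23), IRF1 (0.21 ± 0.17), JAK2 (-0.62 ± 0.22) and CIITA (0.41 ± 0.51) did not pass. Nor did CXCL9, which on 3 counts in TET2 KO cells was higher in WT cells by a ratio of 3.11 (95% counting interval 0.840 to 17.2). CXCL9 had 3 counts in each of these groups once WT untreated replicate 1 was left out. Adjusted p of the genes that did not pass ran from 0.103 for JAK2 to 0.639 for CIITA. JAK2 stood at -0.23 without WT untreated replicate 1 (adjusted p = 0.079), and passed at -0.77 without replicate 2 (adjusted p = 0.0475) and at -0.30 with library weights (adjusted p = 1.22e-04).

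The list of NF-kB targets and regulators was higher in untreated TET2 KO cells, with 18 of 22 members higher and none lower (19 and 0 adjusted over the list alone, median 1.58, camera adjusted p = 3.04e-22). Examples were NFKBIA at 1.83 ± 0.14 and NFKB2 at 2.21 ± 0.19. Of 22 cytokine genes, 10 were higher (15 adjusted over the list alone, median 1.01, adjusted p = 7.68e-11), with the growth factor VEGFA at 2.06 ± 0.16. Of 15 other chemokines, 8 were higher and 1 lower (10 and 1 adjusted over the list alone, median 2.76, or 2.19 with genes at 0 counts at their bounds, adjusted p = 5.58e-10), with CCL5 at 2.19 ± 0.14 and CXCL8 at 2.94 ± 0.33. Of 9 tryptophan, pteridine and itaconate enzymes, 6 were higher (6 adjusted over the list alone, median 1.27, adjusted p = 5.58e-10), with IDO1 at 560.1 times its WT level on 1 count, in replicate 2, of the WT group (95% counting interval 99.99 to 22170). Of 25 Fc receptor and complement genes, 5 were higher and 3 lower (7 and 3 adjusted over the list alone, median 0.26, adjusted p = 0.00471). The list of granulocyte precursor and progenitor genes was lower, with 2 of 23 higher and 5 lower (2 and 7 adjusted over the list alone, median -0.28, adjusted p = 0.00245), the stem cell receptors KIT and FLT3 differing by -3.30 ± 0.32 and -2.08 ± 0.21. These 6 lists also passed with an estimated correlation.

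A further 9 lists passed with the preset correlation and not with an estimated one. The monocyte and macrophage differentiation list had 17 of 40 higher and 4 lower (20 and 6 adjusted over the list alone, adjusted p = 2.66e-09, and adjusted p = 0.0999 with an estimated correlation), with TLR4, a receptor for bacterial lipopolysaccharide, lower at -1.54 ± 0.12. Antiviral genes had 20 of 46 higher and 2 lower (23 and 6 adjusted over the list alone, adjusted p = 2.10e-09, and adjusted p = 0.108 with an estimated correlation), with OASL at 3.86 ± 0.37 and IFITM3 lower at -1.35 ± 0.12. Guanylate-binding proteins and related GTPases had 4 of 9 higher (5 adjusted over the list alone, adjusted p = 1.04e-05, and adjusted p = 0.0622 with an estimated correlation). CXCR3 and PD-1 ligands had 3 of 5 higher (3 adjusted over the list alone, adjusted p = 0.00252, and adjusted p = 0.0828 with an estimated correlation). Phagocyte oxidase genes had 3 of 9 higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.00593, and adjusted p = 0.108 with an estimated correlation). T cell co-signalling ligands had 7 of 23 higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 8.13e-04, and adjusted p = 0.108 with an estimated correlation). The other 3 lists, of hypoxia, immediate early and sterol genes, also passed with the preset correlation only. The lists of MHC class I (3 of 22 higher, adjusted p = 0.134, or 0.0188 without TET2 KO untreated replicate 3) and MHC class II (3 of 19 higher and 1 lower, adjusted p = 0.366) were among the 15 that did not pass. So was the cell cycle list, which passed without WT untreated replicate 1 or TET2 KO untreated replicate 1 or 2 (medians of -0.26, -0.15 and -0.15, adjusted p = 0.017, 0.0384 and 0.0346). In the germline, heat shock and T cell and NK cell lists the median, mean and test differed in sign.

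Other genes with large differences between untreated genotypes were ADAMDEC1, a metalloprotease-like gene of macrophages, at 6.86 ± 0.22, MMP9, a matrix metalloprotease, at 6.35 ± 0.53 (7.27 without WT untreated replicate 2), and SAMSN1 at 5.58 ± 0.22 among those higher. Among those lower were EPHA7, an ephrin receptor, at -4.72 ± 0.30, PGR, the progesterone receptor, at -4.40 ± 0.20, and NCAM1, an adhesion molecule, at -2.99 ± 0.23. The 331 genes induced by IFNγ had a median of 0.67 (122 higher and 13 lower, camera p = 1.87e-23, and p = 0.00145 with an estimated correlation). WT untreated replicate 1 can raise this median, since these genes had a median log2 deviation of -0.61 in it from replicates 2 and 3. That library also took part in choosing them. The 73 repressed genes had a median of -0.58 (23 lower and 6 higher, camera p = 9.42e-07, and p = 0.0742 with an estimated correlation). In total 1663 genes differed, 1013 higher and 650 lower in the knockout, 1000 of them (683 and 317) by at least 1 on the log2 scale. Without WT untreated replicate 1 the number was 4108. It was 1020 or 1054 without TET2 KO untreated replicate 2 or 1, with 73.53% and 73.43% higher, and 412 (297 higher and 115 lower) in a fit of these 2 groups alone. It was 858 at an adjusted p under 0.01, 2637 with DESeq2 and 8375 with library weights, where fewer were higher (4074) than lower (4301).

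**Figure D4:**
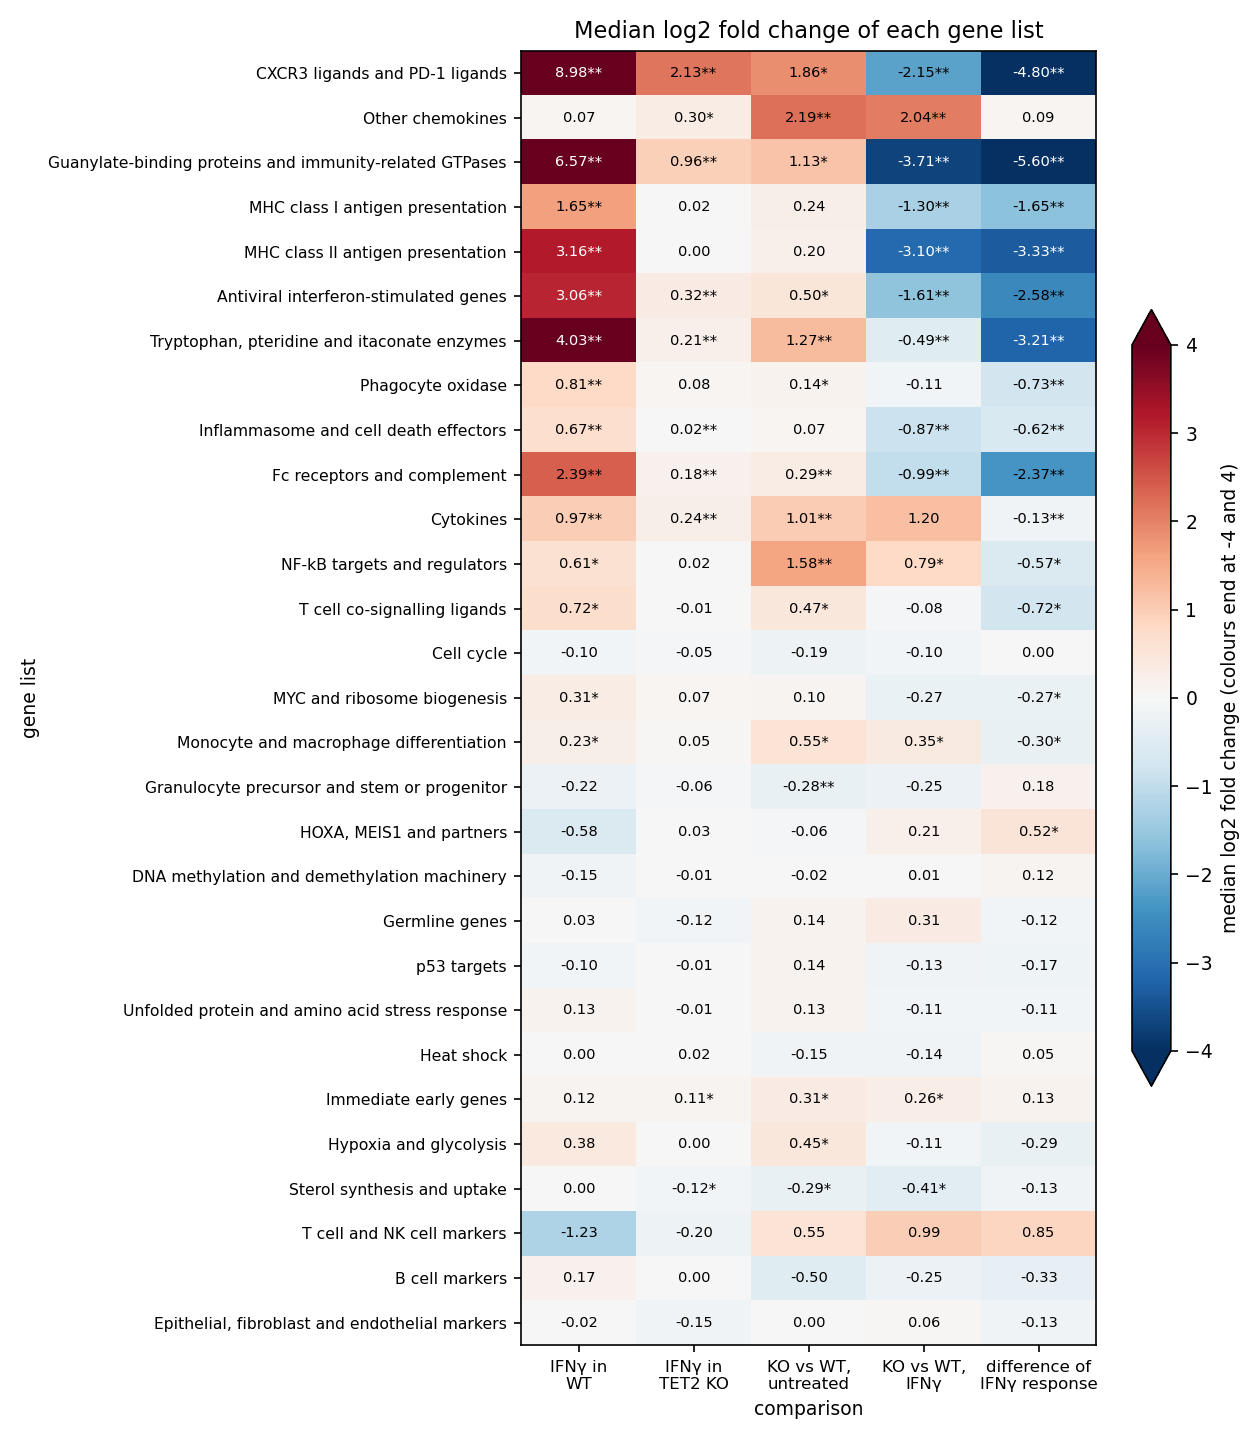
Median log2 fold change of each gene list (rows) in the 5 comparisons (columns), from 3 replicates per group, with genes at 0 counts in a group put at their bounds. An asterisk marks an adjusted camera p under 0.05 with the preset correlation, and a pair of asterisks the same with an estimated correlation as well. The MHC class II list, for example, is at 3.16 with IFNγ in WT cells and at -3.33 for the difference of the response.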

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

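The tests of explanations in this part were chosen after the results were seen. The counts over other splits of the samples were planned.

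The response to IFNγ differed between TET2 KO and WT cells by the test of that difference in 808 genes (3350 without WT untreated replicate 1). Of 82 balanced splits of the 12 replicates in a fit with genotype and treatment, the real split alone gave as many. The highest of the others gave 0. Those splits mix replicates within each group, so the real difference widens their spread and lowers their counts. They therefore cannot decide whether chance differences between the samples gave the count. For the pairwise comparisons, fitted on the 6 replicates of each, the 10 splits are too few for a share under 0.05. The real splits, 1 in each comparison, gave 1034 genes for IFNγ in WT cells, 29 for IFNγ in TET2 KO cells, 412 for the genotypes without IFNγ and 7203 for the genotypes with IFNγ, and the highest of the others gave 0 in each.

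Lists differed by these medians on the log2 scale, TET2 KO minus WT, all with a smaller response in the knockout. These are differences of the change and not of the level with IFNγ. Higher untreated levels in TET2 KO cells enter them for some lists, such as cytokines and tryptophan, pteridine and itaconate enzymes (untreated medians 1.01 and 1.27). The MHC class I and II lists did not pass between untreated genotypes. The median was -4.80 for CXCR3 and PD-1 ligands, -5.60 for guanylate-binding proteins and related GTPases, -1.65 for MHC class I, -3.33 for MHC class II and -2.58 for antiviral genes. It was -3.67 for tryptophan, pteridine and itaconate enzymes, -0.73 for phagocyte oxidase genes, -0.62 for inflammasome and cell death effectors, -2.37 for Fc receptor and complement genes and -0.13 for cytokines. Among genes named in advance, the difference was -4.89 for CXCL10 (-5.65 without WT untreated replicate 1), at most -8.36 for CXCL11, -4.80 for CD274, -3.79 for IRF1, -1.62 for JAK2 and -5.28 for CIITA.

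The small response of TET2 KO cells was weighed as a pattern. The library of WT untreated replicate 1 does not account for the size of the difference, since the median difference of the IFNγ-induced genes was -2.82 without it. That library is in neither TET2 KO group but shares the estimate of the spread. Without it more genes were called in TET2 KO cells, so the small number of calls there does depend on it. RNA of the receptor chains and kinases argues against a lack of them at this level, since the lowest of IFNGR1, IFNGR2, JAK1 and JAK2 in untreated TET2 KO cells, JAK2, lay at -0.62 (-0.23 without WT untreated replicate 1) and IFNGR1 and IFNGR2 were higher than in WT cells by 0.53 and 0.78, although protein was not measured. The induced genes still had a median change of 0.33 in TET2 KO cells. Loss of TET2, another difference between the cell lines or less IFNγ reaching the knockout cells may each underlie it and cannot be told apart, because the labels name no separate knockout clones and no measure of the dose received.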

How the results depend on the processing

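Robust dispersion estimates, library weights in limma-voom and the fit without mitochondrial genes were chosen after seeing the data. The alternatives were run for counts, named genes, lists and sets. For named genes under each alternative, 15450 values kept their side of the threshold, 630 lost the call, 239 gained a call and 1 reversed. Direction was compared only where the main fit or the alternative made a call. Values called in neither were counted as kept, whatever their sign. For lists these numbers were 2101, 38, 34 and 2. For counts, 206 stayed within 1.5 times and 52 moved further. Where no cause follows from the setting itself, as it does for fewer samples, fewer genes or a lower threshold, the cause was not tested.

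Genes called in the 5 comparisons, IFNγ in WT, IFNγ in TET2 KO, TET2 KO against WT without and with IFNγ and the difference of the response, are given in that order. At an adjusted p under 0.01 the numbers were 1348, 12, 858, 1695 and 403, and with a change of at least 1 on the log2 scale 898, 12 and 656 for the first 3 and 368 for the last. Library weights gave 10548, 225, 8375, 9117 and 7185, and with a change of at least 1 they gave 57 in TET2 KO and 1686 for the difference. The weight of WT untreated replicate 1 was 0.0222. With only the 2 groups compared, the numbers were 1034 (725 with a change of at least 1) in WT, 412 (385) without IFNγ and 7203 with IFNγ. With DESeq2 they were 41 in TET2 KO, 2637 without IFNγ and 1548 (931) for the difference. An average log2 CPM of at least 1 left 636 and 1023 genes with a change of at least 1 without and with IFNγ. With replicate number as a block the number in TET2 KO was 15. Among the calls that the block changed were CXCL11 in TET2 KO (1.82, adjusted p = 0.0608, not called) and the cell cycle list without IFNγ (median -0.19, adjusted p = 0.0313, called). The samples were not treated as paired, since 4 of 18 correlations between equal numbers exceeded 0.1, and 4 of 12 samples were most like their own number. Between TET2 KO untreated and TET2 KO IFNγ, however, the correlations were 0.0797, 0.149 and 0.396 for replicates 1, 2 and 3, the last the highest of all. The others over 0.1 were 0.312 and 0.255, between WT untreated and TET2 KO IFNγ, replicates 1 and 3. A pairing within TET2 KO cells is thus not excluded, and a block for these groups alone was not fitted. Library totals alone shifted the median of all genes by 0.10 between untreated genotypes.

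With each replicate left out, the counts ran from 1536 to 6073, 12 to 52, 1020 to 4108, 1874 to 7780 and 484 to 3350, highest without WT untreated replicate 1 in each. With a change of at least 1 they ran from 956 to 1874, 12 to 29, 776 to 1211, 1326 to 2211 and 436 to 1087. TET2 ran from -0.65 to -0.38 in WT, 0.06 to 0.26 in TET2 KO, -0.26 to -0.01 without IFNγ, 0.48 to 0.57 with IFNγ and 0.51 to 0.78 for the difference. The TET2 difference was 0.69 with DESeq2 and 0.59 with library weights, and past the threshold in both. TET2 in WT was -0.52 and not called with only the 2 groups compared, and without IFNγ it was -0.14 and called with library weights. The repressed set without IFNγ kept its median of -0.58 but lost its call with an estimated correlation (p = 0.0742), and with a minimum change of 2, which left 5 genes, it turned to 0.038. The inflammasome and cell death list in TET2 KO ran from -0.017 to 0.068, and was -0.0078 without TET2 KO IFNγ replicate 2 and -0.017 without replicate 3. With library weights XAGE1B with IFNγ in WT turned to 0.19. In simulated data with this depth and 3 replicates per group, at most 55.2% of changes of 2-fold were recovered. The simulated spread was taken from all replicates, WT untreated replicate 1 included, so this is not a limit of depth and replicate number alone.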

Other observations

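All tests of explanations in this part were chosen after the results were seen.

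Metabolic and early response genes differed between the genotypes as well. Without IFNγ, 9 of 25 hypoxia and glycolysis genes were higher in TET2 KO cells (10 adjusted over the list alone, median 0.45, camera adjusted p = 2.59e-04, and adjusted p = 0.17 with an estimated correlation), and 8 of 26 genes of sterol synthesis and uptake were lower (9 adjusted over the list alone, median -0.29, adjusted p = 0.00338, and adjusted p = 0.108 with an estimated correlation). Of 23 immediate early genes, 5 were higher and 2 lower (8 and 2 adjusted over the list alone, median 0.31, adjusted p = 0.0104, and adjusted p = 0.307 with an estimated correlation), a call lost without WT untreated replicate 1 (adjusted p = 0.110). Of 15 heat shock genes 1 was higher (0 adjusted over the list alone, adjusted p = 0.878), and of 22 genes of the unfolded protein and amino acid stress response 4 were higher and 2 lower (6 and 3 adjusted over the list alone, adjusted p = 0.322). Of 40 cell cycle genes 2 were higher and 7 lower (2 and 14 adjusted over the list alone, adjusted p = 0.0696, or 0.0170 without WT untreated replicate 1, and 0.0384 and 0.0346 without TET2 KO untreated replicate 1 and 2).

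Markers of other cell types gave no call as lists. Between untreated genotypes, adjusted p was 0.351 for T cell and NK cell markers (4 tested, 1 higher and 1 lower), 0.45 for B cell markers (4 tested, 1 lower) and 0.339 for epithelial, fibroblast and endothelial markers (5 tested, 1 higher), and of 2 erythroid and megakaryocyte markers, too few for a test, 1 was lower. Differences between genotypes were shared by the treatments beyond the number that independent calls would give. A total of 648 genes were higher in TET2 KO cells both without and with IFNγ, against 103.9 if the calls were independent, and 273 were lower in both, against 52.2. The groups compared share no libraries, and log2 fold changes had r = 0.47 across genes, which are not independent replicates.

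WT untreated replicate 1 stands apart from replicates 2 and 3. Low depth cannot account for it, since replicate 2 thinned to 14.9 M counts gave 1.45 times the Poisson variance against replicate 3, where replicate 1 gave 371, and RNA from IFNγ-treated cells would raise the induced genes, whose median deviation was -0.61. GC content may be part of the difference, since the deviation had a Spearman rho of -0.649 with transcript GC over genes, against -0.481 to 0.592 in the 9 replicates of the other groups, and GC bins held 35.6% of its variance. That comparison was narrowed after a first outcome against GC, in which WT untreated replicates 2 and 3, with rho of 0.649 and 0.638, were included although replicate 1 is among the samples they are set against. WT IFNγ replicate 1 came close with 0.592, although its deviations had an SD of 0.294 against 1.5, no biological explanation was tested, and the rest of the variance has no tested source.

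NF-kB and inflammatory genes were higher in untreated TET2 KO cells, with a median of 1.58 for the NF-kB list. The library of WT untreated replicate 1 does not account for this, since the median was 1.43 without it. RNA carried over from IFNγ-treated WT cells cannot account for it either, since 154 IFNγ-induced genes with a gain of at least 20 CPM in WT showed a median of 2.82% of it in untreated TET2 KO cells (quartiles -0.00672% and 11.3%). The NF-kB list would need a median of 395%, and 14 of its 22 members lay above their level in WT cells with IFNγ. Loss of TET2 and another difference between the cell lines may each underlie it and cannot be told apart, since the labels name no separate knockout clones.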
